A study of Mus musculus with 298 samples.

How the data were processed

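Single cells of the mouse thoracic sympathetic ganglion were taken from Wnt1-Cre by R26R-Tomato mice of both sexes. Per the labels' protocols, ganglia were dissociated with enzymes, cells were cleaned on a density gradient and caught on medium microfluidic chips, the capture sites were inspected by eye, and sites with a single healthy cell were kept. Polyadenylated RNA was turned into cDNA, which was fragmented and barcoded with Tn5 transposase. The deposited table holds a count for each of 16892 genes in each of 298 cells. Per the submitters' processing notes the genome build was mm10, and the aligner, the counting program, the gene annotation and any collapsing of molecules were not stated in the sources used here. Values were whole numbers up to 1888, 704 genes had no count in any cell, and 0 names were of mitochondrial or spike-in genes. Of the gene names, 206 carried a suffix that marks a split entry and 26 had been altered to dates or quoted, and these were kept as they stood.

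Cells were grouped by the identity given in the labels, and 0 table columns were left without a sample. The replicate was the collection, meaning all cells with the same sex and age, because the labels name no animals. Collections held 1 to 106 cells, and those of 1 to 5 cells were labelled P16, P20 and P34 female and P30 male. Median totals per cell in the collections ran from 17828 to 45516. The sexes were caught on 24 chips of 2 lots. The 85 unclassified cells entered no comparison and are described in the closing section.

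For each identity and collection the counts of its cells were summed, which gave 44 libraries. They held 1 to 43 cells. Ach1 libraries were single cells, apart from 2 cells at P31. Glutamatergic libraries held 1 cell (P31 female), 1 cell (P33 female) and 2 cells (P29 male). A collection as replicate is thus often a single cell in the small identities. Whether a block for the collection was warranted was checked in libraries of at least 5 cells. The deviations of 4296 genes from their identity means correlated at 0.173 to 0.226 in the 4 pairs of libraries from the same collection, against a mean of -0.0423 over 20 pairs from different collections, so the collection was kept as a block for this pairing. Identical columns were also looked for, and 0 were found.

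Genes with at least 20 counts in all and a count in at least 3 libraries were kept, 11555 of them. They were scaled by TMM and fitted with edgeR 4.0.16, by robust quasi-likelihood, with a term for each identity and each collection in a single fit. Contrasts weighted each identity equally. F tests were two-sided, p-values were adjusted by Benjamini and Hochberg within a comparison, and genes were called at an adjusted p under 0.05. The SE given for a log2 fold change is its absolute value divided by the square root of its F value. It therefore restates the test and is no separate measure of spread or of counting error. The comparisons were cholinergic against noradrenergic, Glutamatergic against noradrenergic, Ach1 against Ach2, each noradrenergic identity against the other 4, and male against female. For the last, Noradrenergic3 cells were summed in collections with at least 3 of them and sex was the covariate, with 10141 genes tested. Comparisons, alternatives and tests were set before the data were examined, apart from those named as chosen later.

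Identity shares by sex were compared by a two-sided exact permutation test over collections with at least 3 named cells, and total counts per cell by a two-sided exact sign-flip test on collection means of log2 totals. For the held-out test each cell was given the identity whose mean profile, from the other collections, had the highest Spearman correlation with it over the 1000 most variable genes, on log2 of counts per 10000 plus 1.

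Lists of genes were written from general knowledge of these cell types, 23 lists with 292 genes, of which 285 were in the table. They cover catecholamine synthesis, storage and uptake; acetylcholine synthesis, storage and breakdown; glutamate release; neuropeptides and granins; neurotrophic factor and cytokine receptors; sympathetic lineage transcription factors; nicotinic and muscarinic receptors; and adrenergic, purinergic and peptide receptors. Further lists cover voltage-gated channels, neurofilaments and cytoskeleton, synaptic vesicle release, the mitochondrial respiratory chain, immediate-early and stress genes, and the axon injury response. Lists for other cells and for label checks cover satellite glia and Schwann cells, endothelial cells, fibroblasts, macrophages, smooth muscle cells and pericytes, chromaffin and small intensely fluorescent cells, sensory neurons, red blood cells and sex-linked genes. Lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. These p-values were adjusted over the 181 tests of lists by comparisons.

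Named genes were chosen by a rule. It took genes with an adjusted p under 0.05, the same direction without each collection in turn, and a count in at least 50% of cells on the higher side, and named the 8 largest increases and the 6 largest decreases of each comparison. In each comparison up to 10 called list members, taken over all lists together, were added by adjusted p. Th, Dbh, Slc18a2, Slc6a2, Chat, Slc18a3, Slc5a7 and Slc17a6 were added in all cases. For sex, the sex-linked genes and the 10 smallest adjusted p-values were named. The report describes part of these, mostly the stable ones. Where 1 side had 0 counts, a fold is given as a bound against a floor of 3 counts, and where it had 1 to 3 counts a ratio of counts with a 95% exact conditional interval replaces the fitted value. Shares of cells carry 95% Clopper-Pearson intervals, and intervals and floors cover counting error only. Coordinates were looked up in GENCODE M21 on GRCm38, the same assembly as mm10, where 141 of 146 named or listed genes were matched.

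Precision was tested on simulated data. Counts were drawn with the dispersion trend that edgeR estimated, the same for libraries of few and of many cells, and with no collection effect. In data simulated with 200 changed genes, edgeR recovered 53% of 4-fold and 25% of 2-fold changes for the cholinergic contrast, 31% and 1% for the Glutamatergic, 20% and 2% for Ach1 against Ach2, and 70% and 20% for sex. For Noradrenergic1 to Noradrenergic5 it recovered 46%, 75%, 81%, 61% and 67% of 4-fold and 7%, 35%, 43%, 19% and 18% of 2-fold changes, with 0 to 9 unchanged genes called in each of the 9. Most 2-fold changes would therefore have been missed.

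Alternatives tried were RLE size factors, no filter beyond a single count, the filterByExpr filter, a DESeq2 1.42.0 Wald test, limma with voom and quality weights, no block for the collection, at least 2 cells per library, the chip as replicate and block, cells thinned to 26000 counts, no collections younger than day 29, and each collection left out in turn. Thinning left out 22 cells with fewer counts. Others were for sex a single chip lot, no P11 collection and cells of all 8 identities; for shares at least 5 cells per collection or all cells as the denominator; for totals the median or the number of genes; for the held-out test 300 or 3000 genes and held-out chips; and lists without shared members. Added after results were seen were fits without the Ach1 cell richest in Npy, without the Glutamatergic cell richest in Th, with the glial level as a covariate, and shares without the P16 collection. Identities were also shuffled among the cells of all 8 identities within collections, 30 times, and refitted. Some single-gene results and 1 test of an explanation for the Glutamatergic cells are not reported here.

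Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.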

Results

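RNA was counted in 298 single cells from the mouse thoracic sympathetic ganglion, which were caught on 24 microfluidic chips. The mice carried a Wnt1-Cre driver with a Tomato reporter, a cross that marks cells descended from the neural crest. The labels place 213 of the cells in 8 identities and leave 85 unclassified. Of these, 193 were noradrenergic, with 10 cells of Noradrenergic1, 39 of Noradrenergic2, 103 of Noradrenergic3, 18 of Noradrenergic4 and 23 of Noradrenergic5. A further 16 cells were cholinergic, 8 each of Ach1 and Ach2, and 4 cells were Glutamatergic. The cells came from 10 collections, each a single combination of sex and age between postnatal days 11 and 38, with 207 cells in 7 collections labelled female and 91 cells in 3 labelled male. The sex label of the P16 collection, 5 cells labelled female, is in doubt, because they held Y-linked counts and no Xist. Total counts per cell ran from 7225 to 81589 with a median of 33099, and a cell held counts of 2981 to 8465 genes with a median of 6454. Median totals were 35670 in Ach1, 28121 in Ach2, 25756 in Glutamatergic, 27729 in Noradrenergic1, 43245 in Noradrenergic2, 36658 in Noradrenergic3, 33144 in Noradrenergic4 and 35553 in Noradrenergic5. Levels are given as counts per 10000, pooled within each collection, as the mean and SD over collections. On a side with several identities their cells are pooled, so large identities weigh most. Fold changes are fitted with identities weighted equally, so they can differ from the ratio of the levels beside them. The labels do not say how identities were assigned, and identities drawn from these same transcriptomes would make the p-values between them no independent evidence.

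Cholinergic and noradrenergic neurons of the same ganglion were compared to describe how cells with different transmitters differ. Most cholinergic cells held the genes that load and recycle acetylcholine together with the vasodilator peptide Vip, and had far less of the genes that make, store and take back noradrenaline. Vip stood at 84.9 ± 36.1 counts per 10000 (SD, n = 7 collections) against 0.139 ± 0.187 (n = 10), a log2 fold change of 9.50 (SE 0.51, edgeR adjusted p = 9.47e-14). It was higher in 7 of the 7 collections that held both kinds of cell, with a count in 16 of 16 cholinergic cells and 29 of 193 noradrenergic cells. The Ach1 cell richest in Npy, from the P31 female collection, held 61 counts of Th, 63 of Slc6a2 and 586 of Npy with 0 of Chat and of Slc18a3. Slc5a7, the high-affinity choline transporter, stood at 6.72 ± 3.02 against 0.0591 ± 0.0746 (log2 fold change 5.33, SE 0.30, edgeR adjusted p = 1.79e-43). Th, the rate-limiting enzyme of catecholamine synthesis, had a count in 8 of 16 cholinergic cells and in 193 of 193 noradrenergic cells, at 4.27 ± 5.64 against 26.2 ± 2.90 (log2 fold change -4.34, SE 0.63, edgeR adjusted p = 1.64e-05). The cholinergic cells were split, with a Th count in 4 of 8 Ach1 cells. In Ach1 it stood at 9.24 (P31 female), 13.9 (P33 female) and 16.8 (P38 male), and at 0 in the other collections. In Ach2 it stood at 0.487 or less.

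**Figure D1:**
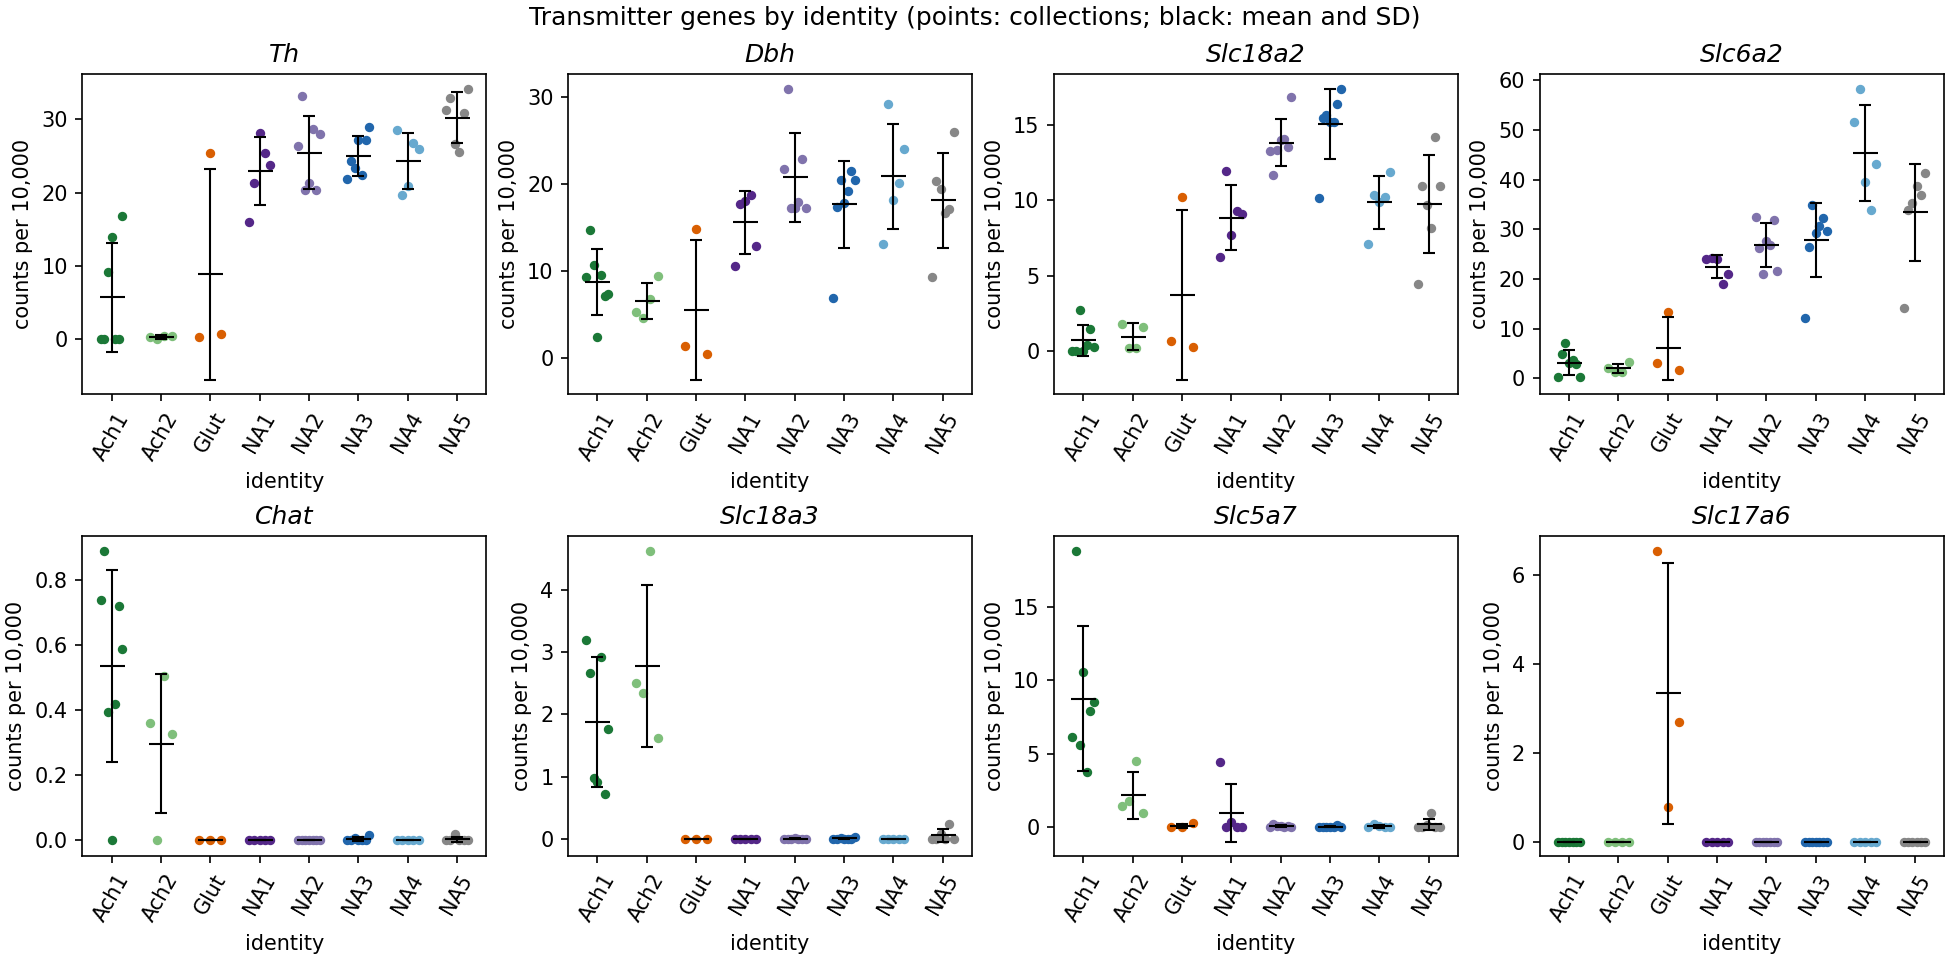
Levels of 8 transmitter genes by identity, in counts per 10000 on the vertical axes, with a point for each collection and the mean and SD over collections in black. The means of Th, Slc18a2 and Slc6a2 are lower in the Ach1, Ach2 and Glutamatergic cells than in the 5 noradrenergic identities, with some overlap of points, and Slc17a6 has counts in the Glutamatergic cells alone.

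In the list of acetylcholine synthesis, storage and breakdown, 3 of 5 measured genes rose, 0 fell and 2 were not called (camera adjusted p = 8.25e-12). Slc18a3, the vesicular acetylcholine transporter, rose by 6.82 on the log2 scale (SE 0.43, edgeR adjusted p = 1.83e-51), with a count in 15 of 16 against 6 of 193 cells. Chat, which makes acetylcholine, had a count in 11 of 16 against 3 of 193 cells, and its 24 counts against 3 gave a level 108-fold higher (95% counting interval 32.8 to 561). Slc18a3 (chromosome 14, 32462438 to 32464850, minus strand; GRCm38) lies inside Chat (32408203 to 32465989, the same strand), so counts near the shared part are uncertain for both. In the list of catecholamine synthesis, storage and uptake, 9 of 12 measured genes fell, 0 rose and 3 were not called (camera adjusted p = 1.24e-19). Slc6a2, the noradrenaline transporter, fell by 3.65 (SE 0.25) on the log2 scale, as did Slc18a2, the vesicular monoamine transporter, with a log2 fold change of -3.87 (SE 0.30), and Ddc, which decarboxylates DOPA, at -2.23 (SE 0.22). Dbh, which turns dopamine into noradrenaline, fell from 19.7 ± 5.52 to 7.72 ± 2.69 counts per 10000 (edgeR adjusted p = 6.94e-11) and kept a count in 16 of 16 cholinergic cells. Adjusted over the list alone, 3 acetylcholine genes and 9 catecholamine genes were called.

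Neuropeptide genes moved both ways in the cholinergic cells, 6 up and 6 down of 19 measured, so the list as a whole was not called (camera adjusted p = 0.745); 14 were called when adjusted over the list alone. Besides Vip, Cartpt rose by 7.81 (SE 0.70) and stood at 12.4 ± 17.2 counts per 10000 (n = 7) against 0.0628 ± 0.0731 (n = 10), and Sst, which encodes somatostatin, rose by 6.49 (SE 0.46) on the log2 scale. Calca, the precursor gene of calcitonin gene-related peptide, had 80 counts against 3, a 360-fold higher level (119 to 1785), and Calcb, a near copy whose reads may be split with it, was 293-fold higher (95.9 to 1457). Gal, which encodes galanin, fell by 5.49 (SE 0.67, edgeR adjusted p = 2.96e-07), with a count in 4 of 16 against 185 of 193 cells, and the granin gene Scg2 fell by 2.80 (SE 0.24). The vasodilator peptide Adm had 1 count against 705, a 52.2-fold lower level (9.33 to 2063).

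Transcription factors of the sympathetic lineage fell in 8 of 16 measured cases, Hand1, Hand2, Gata2 and Isl1 among them, while Sox11 rose (camera adjusted p = 1.1e-05; 13 called when adjusted over the list alone). Insm2, a zinc-finger factor outside that list, had a count in 0 of 16 cholinergic and 150 of 193 noradrenergic cells, at least 9.42-fold lower against a floor of 3 counts over the group. Of 14 receptors for neurotrophic factors and cytokines, 4 rose and 2 fell (camera adjusted p = 0.00226, adjusted p = 0.125 with an estimated correlation; 8 called when adjusted over the list alone). Gfra2, the neurturin co-receptor, rose by 3.19 (SE 0.26, edgeR adjusted p = 1.42e-30). In the synaptic vesicle release list 4 of 18 genes fell, Syt1, Syn2, Cplx2 and Rab3b (camera adjusted p = 0.000168, adjusted p = 0.178 with an estimated correlation; 8 when adjusted over the list alone). Pdlim3, a PDZ and LIM domain protein, rose by 7.33 (SE 0.48), at 2.15 ± 1.66 counts per 10000 (n = 7) against 0.0034 ± 0.00743 (n = 10), and Tmem35, a chaperone of nicotinic receptors, fell by 5.18 (SE 0.58).

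Some glial and stress genes were also higher in the cholinergic cells. Of 14 satellite glia and Schwann cell genes 2 rose, Pmp22 and Sostdc1 (camera adjusted p = 0.00084, adjusted p = 0.434 with an estimated correlation; 2 when adjusted over the list alone). The summed level of that list per cell had a median of 29.5 counts per 10000 in Ach1 and 32.9 in Ach2, against 5.73 over the noradrenergic cells. In the unclassified cells this median was 26.5. Of 19 immediate-early and stress genes 2 rose, Atf3 and Ier3 (camera adjusted p = 0.00303, adjusted p = 0.434 with an estimated correlation; 3 when adjusted over the list alone), and the median stress list level was 18.4 in Ach1, 27.9 in Ach2 and 18.2 in Noradrenergic1. In all, 528 of 11555 genes passed an edgeR adjusted p of 0.05, 251 higher and 277 lower, and the median log2 fold change of all genes was -0.198, against which changes should be read. Leaving out the P29 male collection lowered the count to 348, and DESeq2 did not call Pdlim3 or Calcb.

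**Figure D2:**
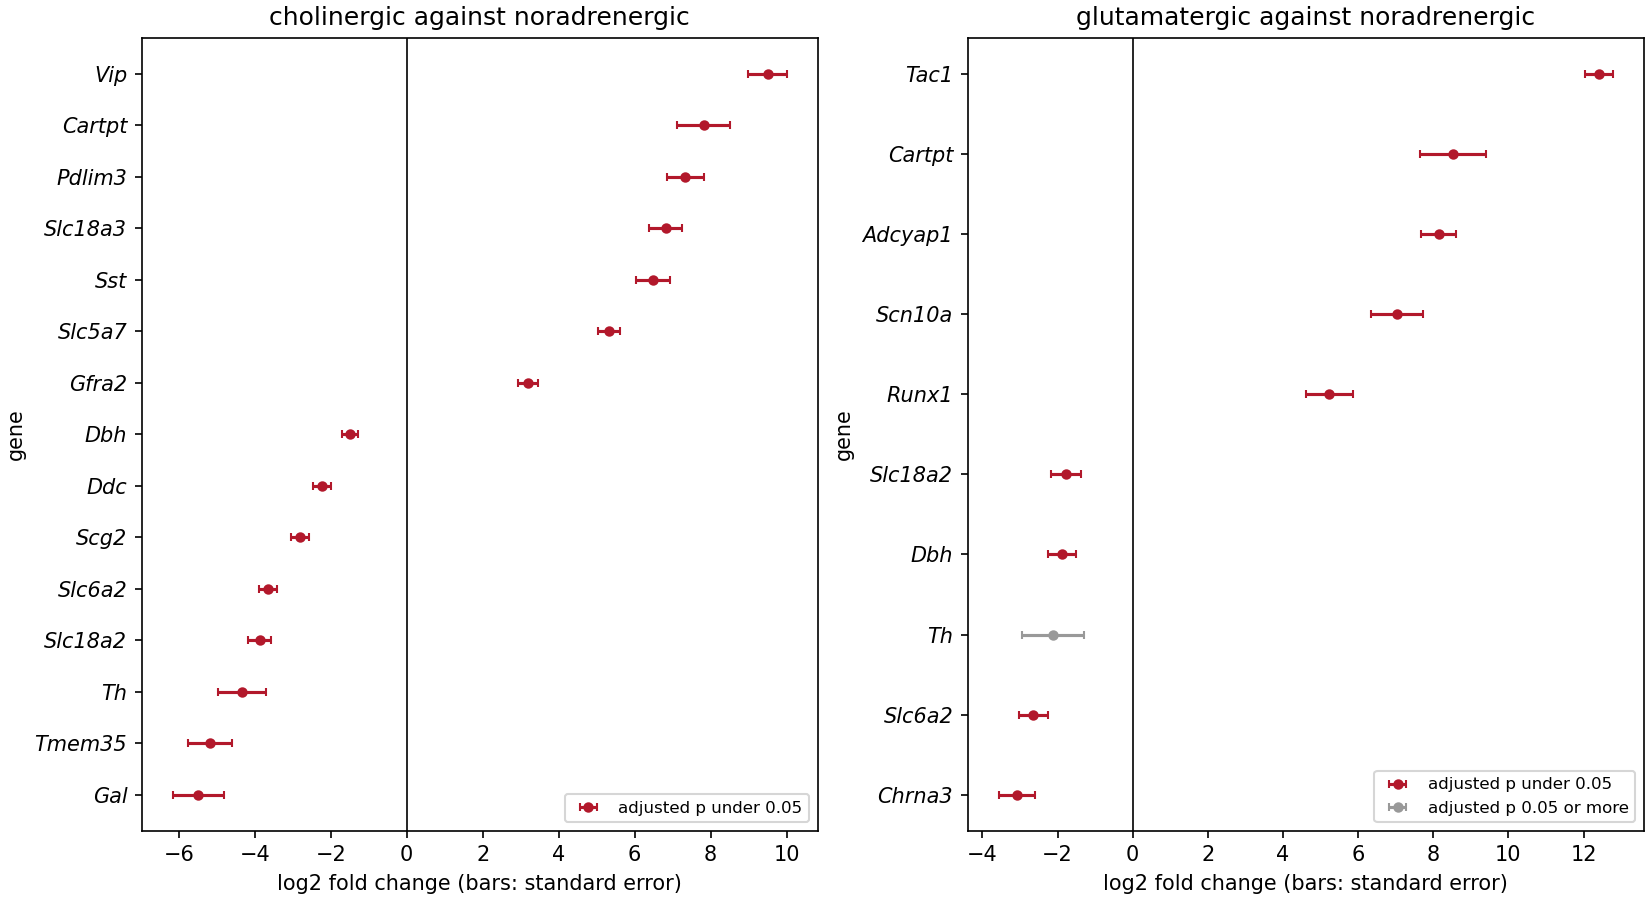
Log2 fold changes with their SE for the named genes with a fitted value, cholinergic against noradrenergic and Glutamatergic against noradrenergic, on horizontal axes centred at 0. Vip is the largest increase in the first comparison and Tac1 in the second, while Slc6a2 lies below 0 in both. The SE is derived from the F test.

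Glutamatergic cells were compared with noradrenergic cells to describe the 4 cells whose label names a transmitter not expected of sympathetic output neurons. They held sensory peptides, a vesicular glutamate transporter and a nociceptor sodium channel, and 3 of the 4 cells held little of Th, Dbh and Slc6a2. Calca stood at 113 ± 46.2 counts per 10000 (n = 3 collections) against 0.000907 ± 0.00287 (n = 10), with counts in 4 of 4 against 2 of 193 cells. Tac1, which encodes substance P, stood at 38.8 ± 13.2 against 0.00597 ± 0.0150 (log2 fold change 12.41, SE 0.37, edgeR adjusted p = 3.67e-237). This p-value and the SE derived from its test use an estimate of spread shared by all identities. They do not measure replication among the 4 Glutamatergic cells. Slc17a6, the vesicular glutamate transporter VGLUT2, stood at 3.35 ± 2.94 against 0, with a count in 4 of 4 Glutamatergic cells, 0 of 193 noradrenergic cells and 0 of 16 cholinergic cells. That is at least 689-fold higher against a floor of 3 counts over the group. Of the 34 counts 19 came from the P31 female cell, so the size of this bound rests largely on that cell.

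Markers of sensory neurons rose in 4 of 6 measured cases, Scn10a, Runx1, P2rx3 and Tac1 (camera adjusted p = 1.31e-12; 5 when adjusted over the list alone). Scn10a, the sodium channel of nociceptors, rose by 7.04 (SE 0.69, edgeR adjusted p = 3.46e-21) and Runx1, a transcription factor of nociceptors, by 5.23 (SE 0.62, edgeR adjusted p = 1.97e-14) on the log2 scale. Of 19 neuropeptide and granin genes 6 rose and 1 fell (camera adjusted p = 1.3e-08; 8 when adjusted over the list alone). These included Adcyap1, the precursor gene of PACAP, which rose by 8.14 (SE 0.47), and Cartpt, which rose by 8.52 (SE 0.87). In the glutamate release list 1 of 3 measured genes rose, Slc17a6 (camera adjusted p = 0.0378, adjusted p = 0.134 with an estimated correlation; 1 when adjusted over the list alone), and the list's median fold change was below 0 while its mean and its test were above.

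Catecholamine genes fell in 7 of 12 measured cases (camera adjusted p = 1.01e-13; 8 when adjusted over the list alone). Slc6a2 fell by 2.64 (SE 0.39, edgeR adjusted p = 6.56e-09) and stood at 6.04 ± 6.33 against 28.3 ± 5.72, Dbh fell by 1.89 (SE 0.37) and Slc18a2 by 1.78 (SE 0.40). Dbh was not called without the P31 female collection, where it had a log2 fold change of -1.34, or without the P29 male collection, at -1.24. Slc18a2 in glutamatergic against noradrenergic cells was not called without these collections either, at -1.20 and -1.25, or without the P30 male collection, at -1.75, and its call also ended with filterByExpr, with no block and with the chip as block. Th was not called, with a log2 fold change of -2.12 (SE 0.83, edgeR adjusted p = 0.253), and the 4 cells were split. The cell from the P33 female collection held 130 counts of Th, 76 of Dbh, 68 of Slc6a2 and 555 of Npy beside 313 of Calca and 122 of Tac1, whereas the other 3 cells held 0 to 3 counts of Th. Th in glutamatergic against noradrenergic cells was called without the P33 collection, at -5.85, and by DESeq2 with all cells, at -2.77. With at least 2 cells per library the log2 fold change of Th was -5.36. That fit kept the P29 male library alone on the Glutamatergic side and so also lacked the P33 cell.

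**Figure D3:**
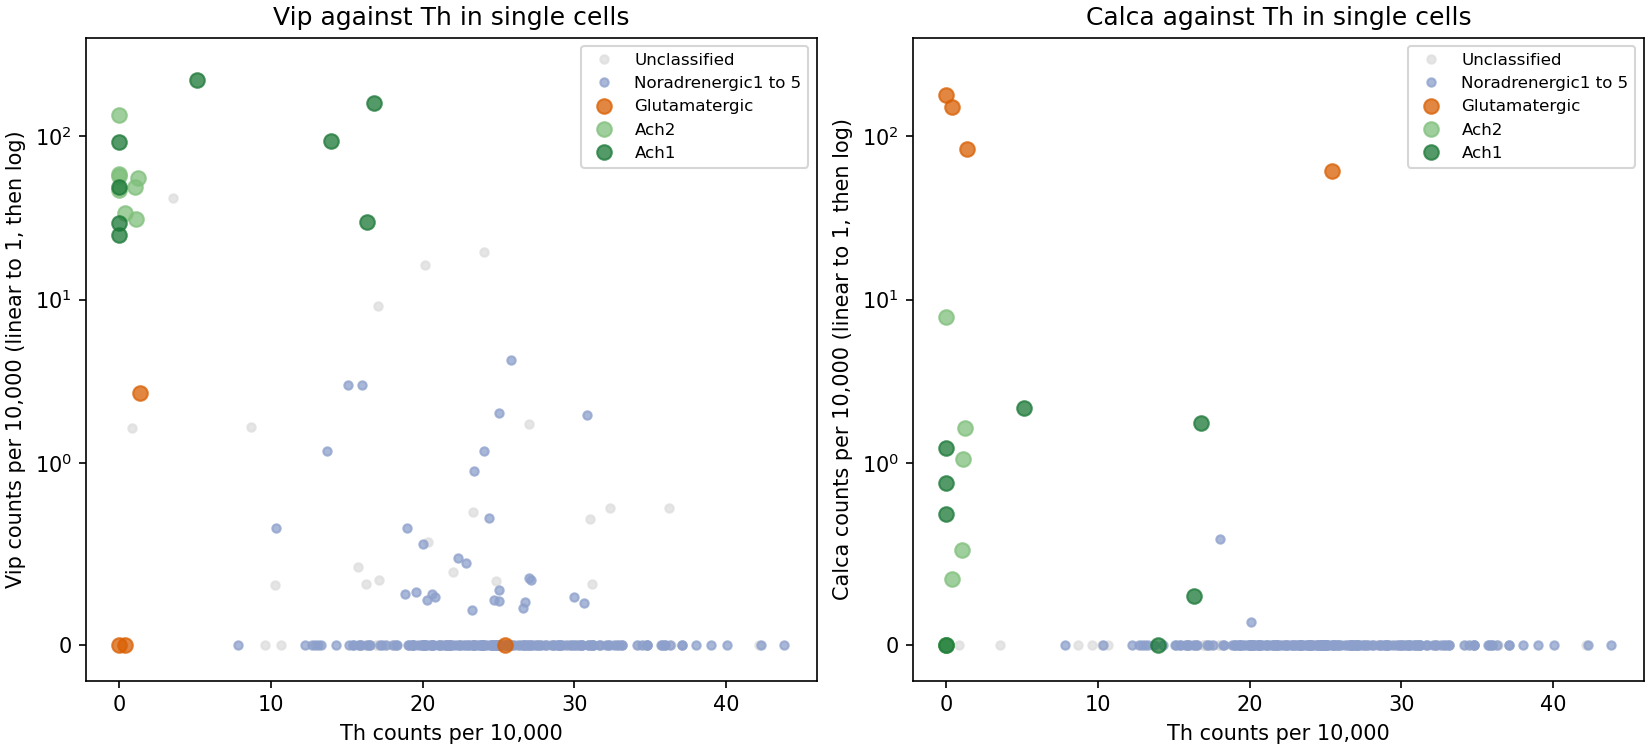
Counts per 10000 of Vip against Th and of Calca against Th in each cell, with the vertical axes linear near 0 and logarithmic above. Glutamatergic cells lie high on the Calca axis, and 1 of the 4 lies among the noradrenergic cells on the Th axis at 25.4.

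Of 16 measured sympathetic lineage transcription factors 6 fell, Hand1, Hand2 and Gata3 among them, and 0 rose (camera adjusted p = 3.9e-05; 7 when adjusted over the list alone). Nicotinic and muscarinic receptors fell in 2 of 7 measured cases (camera adjusted p = 0.000168; 4 when adjusted over the list alone), and Chrna3, the main ganglionic nicotinic subunit, fell by 3.08 (SE 0.49, edgeR adjusted p = 1.15e-07). Agtr1a, the angiotensin II receptor, had a count in 0 of 4 against 177 of 193 cells, at least 6.05-fold lower. Of 18 synaptic vesicle release genes 4 fell, Syt1, Syn2, Cplx2 and Rab3b (camera adjusted p = 2.59e-07, adjusted p = 0.0668 with an estimated correlation; 6 when adjusted over the list alone). The neurofilament and cytoskeleton list was called lower with 0 of 15 genes called (camera adjusted p = 0.0429, adjusted p = 0.645 with an estimated correlation; 0 when adjusted over the list alone). The mitochondrial respiratory chain list was called lower with 0 of 20 genes called (camera adjusted p = 0.00285, adjusted p = 0.685 with an estimated correlation; 0 when adjusted over the list alone).

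Immediate-early and stress genes rose in 2 of 19 cases, Jun and Btg2 (camera adjusted p = 1.03e-05, adjusted p = 0.161 with an estimated correlation; 7 when adjusted over the list alone), and the list's summed level per cell had a median of 48.1 counts per 10000 against 10.0 in Noradrenergic4 to 18.2 in Noradrenergic1. The glial list was called higher with 0 of 14 genes called (camera adjusted p = 0.00904, adjusted p = 0.617 with an estimated correlation; 0 when adjusted over the list alone), at a median of 28.9 per cell. In all, edgeR called 304 of 11555 genes, 187 higher and 117 lower, with a median log2 fold change over all genes of -0.386, or -0.505 with RLE size factors. The count was 91 without the P31 female collection and 97 without the P29 male collection, and DESeq2 called 35 higher and 262 lower and did not call Tac1. Calls of Slc17a6 ended with the chip as block or the glial level as a covariate, with the same 34 counts against 0 in each. That of Agtr1a ended with at least 2 cells per library, which kept the P29 male Glutamatergic library alone. It also ended with thinned cells, which left out the P29 male Glutamatergic cells, so both fits held fewer of these cells. A further 5 named decreases ended without the P31 female or the P29 male collection.

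Ach1 and Ach2 were compared to describe the 2 cholinergic identities. They differed most in Sst, which was far higher in Ach2, at 19.6 ± 8.06 counts per 10000 (n = 4 collections) against 0.624 ± 0.814 in Ach1 (n = 7), a log2 fold change of -4.87 (SE 0.36, edgeR adjusted p = 1.19e-37). Sst was lower in Ach1 in 4 of 4 collections and had a count in 8 of 8 Ach2 and 5 of 8 Ach1 cells. The choline transporter Slc5a7 was higher in Ach1 by 1.88 (SE 0.36, edgeR adjusted p = 0.000958), with a count in all 16 cells. It was not called without the P30 female collection, at 1.36, or without the P38 male collection, at 1.65. The Slc5a7 call also ended with filterByExpr, with voom, with no block and with at least 2 cells per library. The last of these kept the P31 female library alone for Ach1. Fam122b was higher in Ach1 by 3.75 (SE 0.62), a call that ended with the chip as block (2.80) or with thinned cells (2.99).

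Of 11555 genes edgeR called 16 between Ach1 and Ach2, 5 higher and 11 lower, and 856 had an unadjusted p under 0.05. Sst was the single call among the 13 named genes called here that held in all alternatives and without each collection, and the count fell to 5 without the P38 male collection. The mitochondrial respiratory chain list was called lower in Ach1 with 0 of 20 genes called (camera adjusted p = 0.00226, adjusted p = 0.685 with an estimated correlation; 1 when adjusted over the list alone). Th stood at 5.71 ± 7.45 in Ach1 and 0.312 ± 0.215 in Ach2 and was not called (edgeR adjusted p = 0.479).

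Each noradrenergic identity was compared with the other 4 to describe how noradrenergic neurons divide. All 193 noradrenergic cells held counts of Th, Dbh, Slc18a2 and Slc6a2, and the identities differed in other genes. Among the transmitter genes, Slc18a2 was higher in Noradrenergic3 by 0.72 (SE 0.21, edgeR adjusted p = 0.0348) and Slc6a2 in Noradrenergic4 by 0.82 (SE 0.24, edgeR adjusted p = 0.0435). Slc18a2 was not called without the P11 female (0.66), P30 female (0.67), P29 male (0.68), P30 male (0.72) or P38 male (0.73) collections. Slc6a2 was not called without the P11 female (0.61), P30 female (0.67), P31 female (0.92), P29 male (0.85) or P38 male (0.82) collections. The Slc18a2 call also ended in 4 of 10 other alternatives, filterByExpr, DESeq2, no block and no young collections. The Slc6a2 call ended in 8 of 10, and held with no filter and with at least 2 cells per library.

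**Figure D4:**
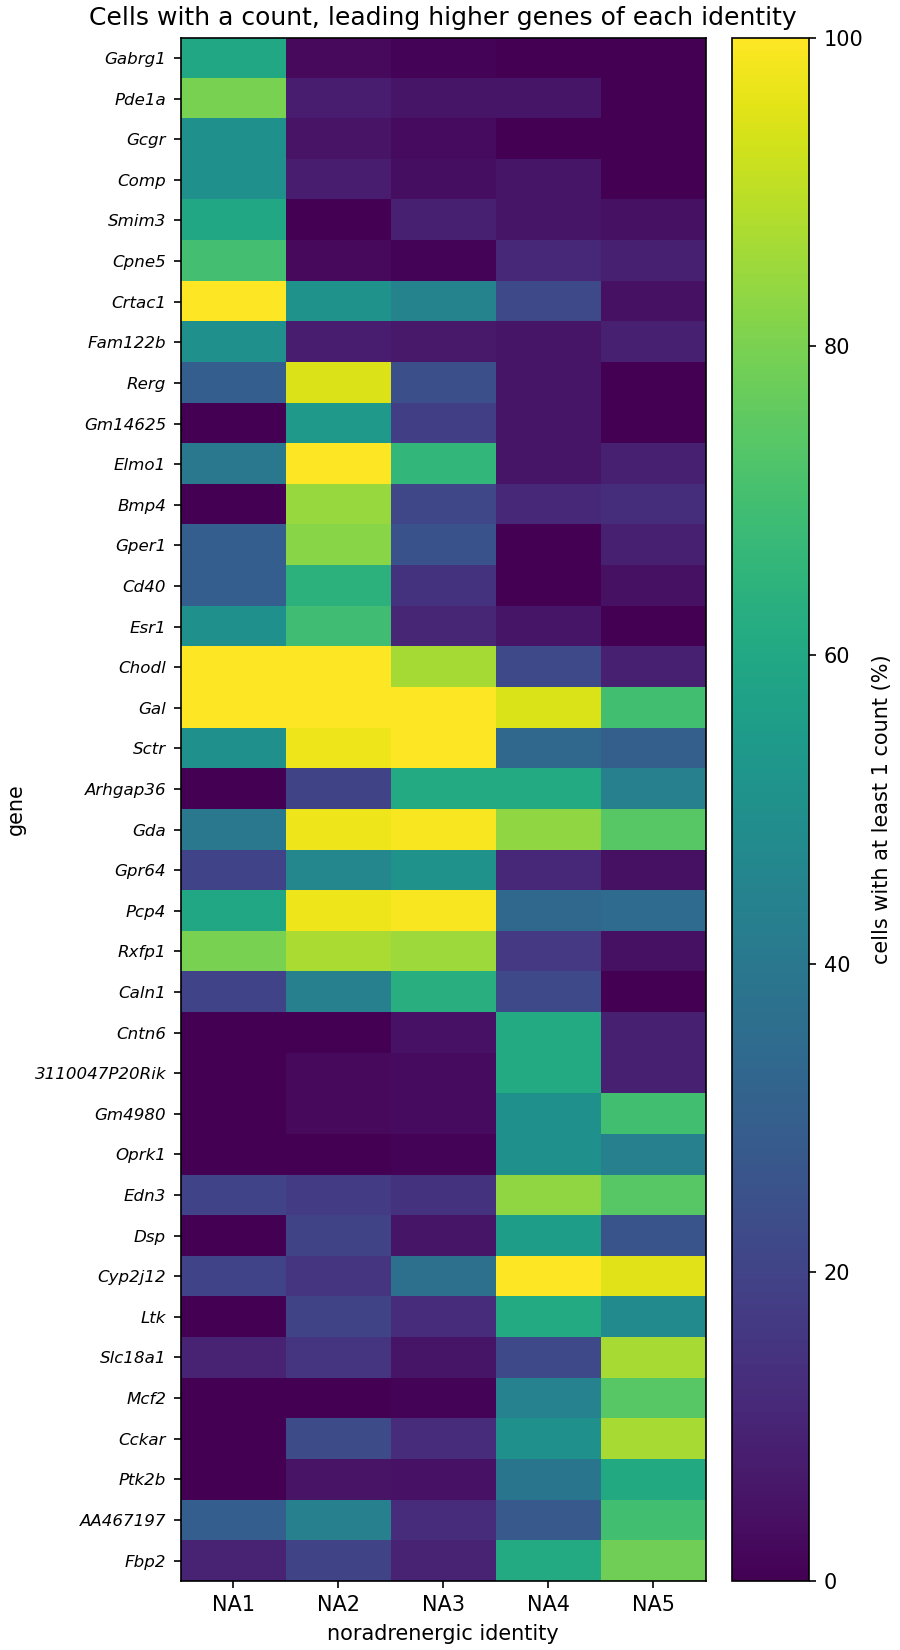
Percent of cells with a count of the leading higher genes of each noradrenergic identity, with genes on the vertical and identities on the horizontal axis. Rerg has a count in 37 of 39 Noradrenergic2 cells and Slc18a1 in 20 of 23 Noradrenergic5 cells.

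Noradrenergic1, with 10 cells in 5 collections, was marked by Gabrg1, a GABA-A receptor subunit, and by Pde1a, a calcium-dependent phosphodiesterase. Gabrg1 stood at 1.52 ± 0.922 counts per 10000 (n = 5) against 0.00179 ± 0.00434 (n = 9), and its 34 counts against 2 gave a 413-fold higher level (106 to 3550). Pde1a stood at 2.02 ± 1.67 against 0.0139 ± 0.0205 (log2 fold change 6.25, SE 0.50, edgeR adjusted p = 3.04e-32). Gcgr, the glucagon receptor, rose by 6.15 (SE 0.77) and Crtac1, a matrix protein, by 4.71 (SE 0.35), with a Crtac1 count in 10 of 10 against 71 of 183 cells. The calcium-binding protein gene Necab1 had a count in 0 of 10 against 97 of 183 cells, at least 4.16-fold lower, and Tenm4 fell by 3.97 (SE 0.60) and Agtr1a by 3.53 (SE 0.56).

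In Noradrenergic1, 3 of 18 synaptic vesicle release genes fell, Syt1 by 1.61 (SE 0.28), Cplx2 by 1.67 (SE 0.32) and Cplx1 (camera adjusted p = 0.0109, adjusted p = 0.473 with an estimated correlation; 4 when adjusted over the list alone). The catecholamine list was called lower with 0 of 12 genes called (camera adjusted p = 0.00787, adjusted p = 0.473 with an estimated correlation; 4 when adjusted over the list alone). In all, 161 of 11555 genes were called by edgeR, 100 higher and 61 lower, with a median log2 fold change of -0.149 over all genes, and DESeq2 called 47 higher and 75 lower. Cplx1 in Noradrenergic1 against other noradrenergic cells was not called without the P38 male collection, at -1.39. The count was 102 without the P31 female, 90 without the P29 male and 92 without the P38 male collection.

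Noradrenergic2, with 39 cells in 7 collections, was higher in Rerg, a Ras-like growth regulator, and Elmo1, which acts in Rac activation. Rerg stood at 0.790 ± 0.304 counts per 10000 (n = 7) against 0.110 ± 0.0803 (n = 8), a log2 fold change of 4.11 (SE 0.42, edgeR adjusted p = 2.1e-18), with a count in 37 of 39 against 29 of 154 cells. Elmo1 stood at 1.15 ± 0.222 against 0.254 ± 0.150 (log2 fold change 3.73, SE 0.35, edgeR adjusted p = 1.24e-22). Bmp4, a growth factor, rose by 3.54 (SE 0.47), the membrane oestrogen receptor Gper1 by 3.23 (SE 0.50) and the nuclear oestrogen receptor Esr1 by 3.00 (SE 0.53). The surface glycoprotein Thy1 fell by 2.73 (SE 0.35) and stood at 0.374 ± 0.355 against 3.14 ± 0.972.

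Of 19 neuropeptide and granin genes 3 rose in Noradrenergic2, Sst, Chgb and Nmu (camera adjusted p = 0.00226, adjusted p = 0.0668 with an estimated correlation; 5 when adjusted over the list alone). The glial list was called lower with 0 of 14 genes called (camera adjusted p = 0.0429, adjusted p = 0.685 with an estimated correlation; 0 when adjusted over the list alone). In all, edgeR called 189 of 11555 genes, 157 higher and 32 lower, against 112 higher and 149 lower with voom, and calls with shuffled identities were higher in 93.5%. DESeq2 did not call Esr1 or Sst, and the Sst call also ended with voom or thinned cells. In Noradrenergic2 against other noradrenergic cells, Chgb was not called without the P38 male collection (0.75). Nmu was not called without the P30 female (2.17), P31 female (2.53), P33 female (2.21), P29 male (2.21) or P38 male (2.80) collections. The count was 114 without the P31 female and 118 without the P29 male collection.

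Noradrenergic3, the largest identity with 103 cells in 7 collections, was richest in the peptide Gal and in the receptor Sctr. Gal stood at 34.5 ± 8.06 counts per 10000 (n = 7) against 8.12 ± 6.13 (n = 10), a log2 fold change of 2.60 (SE 0.33, edgeR adjusted p = 2.34e-06), higher in 7 of 7 collections. Sctr, the secretin receptor, stood at 5.22 ± 0.959 against 1.55 ± 1.01 (log2 fold change 2.56, SE 0.37, edgeR adjusted p = 4.83e-05). Chga, a granin of secretory vesicles, rose by 1.98 (SE 0.18), the relaxin receptor Rxfp1 by 2.41 (SE 0.33) and Gfra3, the artemin co-receptor, by 2.01 (SE 0.33). The subunits of the serotonin-gated channel were lower, Htr3a by a log2 fold change of -2.81 (SE 0.50) and Htr3b of -2.12 (SE 0.27), and Htr3a stood at 0.350 ± 0.320 against 3.95 ± 3.18. The transcription factor Tbx3 fell by 1.96 (SE 0.29) and the adrenergic receptor Adra2a by 1.69 (SE 0.27).

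Of 19 neuropeptide and granin genes 3 rose in Noradrenergic3, Gal, Chga and Chgb (camera adjusted p = 0.00848, adjusted p = 0.107 with an estimated correlation; 7 when adjusted over the list alone), and the latter pair are 2 of the 4 measured chromaffin cell genes (camera adjusted p = 0.0378, adjusted p = 0.134 with an estimated correlation; 3 when adjusted over the list alone). In the axon injury list 3 of 11 genes rose, Gal, Ecel1 and Anxa1 (camera adjusted p = 0.0357, adjusted p = 0.199 with an estimated correlation; 5 when adjusted over the list alone). Of 7 nicotinic and muscarinic receptors 2 rose, Chrna7 and Chrm2 (camera adjusted p = 0.0344, adjusted p = 0.161 with an estimated correlation; 2 when adjusted over the list alone). Of 3 measured smooth muscle and pericyte genes 2 rose, Rgs5 and Myh11 (camera adjusted p = 0.0172, adjusted p = 0.199 with an estimated correlation; 3 when adjusted over the list alone). That list had a median of 0.153 counts per 10000 per cell and a highest cell at 15.3, and Flt1, Col3a1 and Lum from the endothelial and fibroblast lists also rose. In all, edgeR called 201 of 11555 genes, 169 higher and 32 lower, with a median log2 fold change of 0.164 over all genes. The count was 117 without the P31 female and 124 without the P38 male collection; voom called 139 higher and 538 lower, and DESeq2 did not call Chrna7.

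Noradrenergic4, with 18 cells in 5 collections, was higher in Cntn6, a neural adhesion molecule, and in 4 of 14 receptors for neurotrophic factors and cytokines. Cntn6 stood at 0.378 ± 0.269 counts per 10000 (n = 5) against 0.00421 ± 0.00689 (n = 10), a log2 fold change of 5.25 (SE 0.73, edgeR adjusted p = 7.35e-10). Edn3, which encodes endothelin 3, rose by 3.62 (SE 0.55) and Cyp2j12, a member of a cytochrome P450 family whose reads may be shared, by 3.19 (SE 0.33), with a Cyp2j12 count in 18 of 18 against 68 of 175 cells. Cpne8, a copine, stood at 0.179 ± 0.220 against 2.12 ± 1.46 (log2 fold change -2.97, SE 0.44, edgeR adjusted p = 2.14e-08). Of 14 neurotrophic factor and cytokine receptors 4 rose, Gfra2 by 2.39 (SE 0.34), Lifr by 1.61 (SE 0.26), Ret by 1.40 (SE 0.23) and Ngfr (camera adjusted p = 0.029, adjusted p = 0.226 with an estimated correlation; 5 when adjusted over the list alone). Ngfr in Noradrenergic4 against other noradrenergic cells was not called without the P11 female (0.71) or P30 female (0.78) collection, or in 6 other alternatives.

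Adra2a, an inhibitory adrenergic receptor, rose by 1.75 (SE 0.28, edgeR adjusted p = 3.57e-07) in Noradrenergic4. The mitochondrial respiratory chain list was called lower with 0 of 20 genes called (camera adjusted p = 4.22e-08, adjusted p = 0.349 with an estimated correlation; 1 when adjusted over the list alone). In the glial list 1 of 14 genes rose, Pmp22 (camera adjusted p = 0.0279, adjusted p = 0.685 with an estimated correlation; 1 when adjusted over the list alone), at a median glial level of 10.3 per cell. In all, edgeR called 145 of 11555 genes, 110 higher and 35 lower. The count was 87 without the P31 female and 96 without the P38 male collection, and the calls of Lifr and Pmp22 ended with thinned cells.

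Noradrenergic5, with 23 cells in 6 collections, was higher in Slc18a1, a vesicular monoamine transporter best known from endocrine cells, and in Cckar, a cholecystokinin receptor. Slc18a1 stood at 1.21 ± 0.811 counts per 10000 (n = 6) against 0.0267 ± 0.0368 (n = 10), a log2 fold change of 4.73 (SE 0.43, edgeR adjusted p = 3.78e-24), with a count in 20 of 23 against 17 of 170 cells. Cckar stood at 0.971 ± 0.521 against 0.0405 ± 0.0625 (log2 fold change 4.20, SE 0.48). Chodl, which encodes chondrolectin, had 2 counts against 1502, a 94.9-fold lower level (26.2 to 785), and Tmem255b had a count in 0 of 23 against 120 of 170 cells, at least 12.3-fold lower. Gal fell by 4.16 (SE 0.58, edgeR adjusted p = 1.45e-05) and Fst, which encodes follistatin, with a count in 2 of 23 against 156 of 170 cells, also fell.

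Of 19 neuropeptide and granin genes in Noradrenergic5, Scg2 rose and Gal and Chgb fell (camera adjusted p = 0.0306, adjusted p = 0.179 with an estimated correlation; 6 when adjusted over the list alone). In the axon injury list 2 of 11 genes fell, Gal and Ecel1 (camera adjusted p = 0.0306, adjusted p = 0.178 with an estimated correlation; 3 when adjusted over the list alone). Of 11 adrenergic, purinergic and peptide receptors 3 rose, Agtr1a by 1.38 (SE 0.27), Adra2a by 1.39 (SE 0.28) and Npy2r, a neuropeptide Y receptor, with 16 counts against 3 (camera adjusted p = 0.0386, adjusted p = 0.125 with an estimated correlation; 3 when adjusted over the list alone), and the list's median fold change was below 0 while its mean and its test were above. The acetylcholine list was called higher with 0 of 5 genes called (camera adjusted p = 0.00347, adjusted p = 0.161 with an estimated correlation; 3 when adjusted over the list alone). Of 7 fibroblast genes 4 rose, Col1a1, Col1a2, Lum and Mgp (camera adjusted p = 0.000702, adjusted p = 0.262 with an estimated correlation; 7 when adjusted over the list alone), and Col1a1 had a count in 3 of 23 against 13 of 170 cells. The Col1a1 call ended in 6 of 9 alternatives and the Lum call in 3 of 8. In all, edgeR called 163 of 11555 genes, 91 higher and 72 lower. The count was 56 without the P31 female collection, DESeq2 called 36 higher and 50 lower and did not call Cckar, and Adra2a (1.35), Lum (1.21) and Ecel1 in Noradrenergic5 against other noradrenergic cells (-1.79) were not called without the P31 female collection, nor Col1a1 without the P30 female collection (0.54).

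Male and female cells of Noradrenergic3, the largest identity, differed in sex-linked genes. Xist, the transcript of X inactivation, had 854 counts in 75 of 75 female cells and 0 in 28 male cells, at least 104-fold higher in females, and Tsix had 491 against 0, at least 60.1-fold higher. Xist (X chromosome, 103460366 to 103483254, minus strand; GRCm38) and Tsix (103431517 to 103484957, plus strand) overlap on opposite strands, so their counts are uncertain. The Y-linked Ddx3y had 116 counts in 27 of 28 male cells and 1 in 75 female cells, a ratio of 316 (55.6 to 12585, edgeR adjusted p = 2.76e-11), and Eif2s3y had 55 against 0, at least 49.9-fold higher in males. Uty had 17 counts against 0, at least 15.4-fold higher.

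Of 10141 genes tested in 2 male and 5 female collections edgeR called 3, Ddx3y higher in males and Xist and Tsix lower, and 290 had an unadjusted p under 0.05. The filter asked for a count in at least 3 libraries, so genes with counts in the 2 male libraries alone, such as Eif2s3y and Uty, were not tested. Ddx3y was tested through its 1 count in a female cell. The split of calls, here and within a single chip lot, is therefore tilted against genes higher in males. Of the 3 sex-linked genes tested 1 rose and 2 fell (camera adjusted p = 1.05e-11, adjusted p = 0.0588 with an estimated correlation; 3 when adjusted over the list alone). Fibroblast genes were called lower in males with 0 of 7 called (camera adjusted p = 0.0357, adjusted p = 0.685 with an estimated correlation; 0 when adjusted over the list alone), as were smooth muscle and pericyte genes with 0 of 3 called (camera adjusted p = 0.0166, adjusted p = 0.199 with an estimated correlation; 1 when adjusted over the list alone). The count was 6 without the P29 male collection, 8 without the filter, 15 within a single chip lot (1 higher, 14 lower) and 12 over all identities. Sex was partly confounded with age and chip, and 0 male cells came from outside the chip lot that held both sexes.

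The share of each identity among named cells was compared between the sexes, and 0 of 8 identities were called by a test too small to call any single one. The smallest value was for Noradrenergic1, at 26.8 ± 34.5% in 3 collections labelled male and 1.29 ± 2.03% in 6 labelled female, the P16 collection among them (two-sided exact permutation p = 0.0119, the smallest that 84 regroupings allow, adjusted p = 0.0952 over 8 identities). The male mean rests on the P30 collection, where 2 of 3 named cells were Noradrenergic1, against 2 of 28 at P29 and 2 of 30 at P38. Total counts per cell were called in 0 of 8 comparisons, and with these numbers of collections none could have been called after adjustment. Noradrenergic1 was lower in 4 of 4 collections (two-sided exact sign-flip permutation p = 0.125, the smallest possible). The smallest value was for Noradrenergic2, higher in 5 of 5 collections by 0.39 on the log2 scale (SD 0.20; two-sided exact sign-flip permutation p = 0.0625, the smallest that 5 collections allow, adjusted p = 0.5 over 8 comparisons).

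When each collection was held out in turn, the nearest identity profile from the other collections matched the label in 177 of 213 cells, 83.1% (95% Clopper-Pearson interval 77.4 to 87.9), against a median of 60 cells and at most 77 in 100 shuffles of identities within collections. Identities drawn from these same cells would make such a recovery in part built in. Noradrenergic2 was recovered in 38 of 39 cells, Noradrenergic3 in 90 of 103, Noradrenergic5 in 19 of 23, Noradrenergic1 in 7 of 10, Ach1 in 5 of 8, Ach2 in 8 of 8 and Glutamatergic in 3 of 4. Noradrenergic4 was recovered in 7 of 18 cells, and 9 of its cells were nearest to Noradrenergic5.

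Voltage-gated channels were called as a list in 0 of the comparisons by camera, with 22 genes measured in the comparisons of identities. Their smallest unadjusted camera p was 0.0498, for Ach1 against Ach2 (adjusted p = 0.17), and fry gave an adjusted p of 0.696 there. In the Glutamatergic cells 3 members rose and 1 fell, Kcna2 and Scn3a among them (camera adjusted p = 0.359; 6 when adjusted over the list alone). Endothelial genes, with 4 measured in the comparisons of identities, were also called as a list in 0 comparisons, with a smallest unadjusted camera p of 0.159 for Noradrenergic3 (adjusted p = 0.381), where Flt1 rose, and fry gave an adjusted p of 0.103 there. Macrophage and red blood cell genes had too few measured members for a list test.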

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

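The tests of explanations in this part were chosen after the results were seen. A value was picked out when it lay far from the others of its group, when a difference changed with sex, or when a signal appeared in cells outside the comparisons; of 137 groups searched for a distant value 34 were picked out, where chance would pick out about 1 in 20 of groups with normal spread, a rate not checked for groups with few counts.

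The 4 Glutamatergic cells held sensory genes, and 3 of them little of the noradrenergic ones. A noradrenergic cell sharing a well with a sensory cell is argued against for 3 of them, whose highest catecholamine list level was 14.9% of the median noradrenergic cell. It remains possible for the cell of the P33 female collection, at 68.9%. A Glutamatergic cell was found in 3 of 5 collections with at least 20 named cells, by which a glutamatergic neuron type of the ganglion itself and cells carried in with the dissection cannot be told apart. Sensory neurons from a neighbouring ganglion were not excluded by any test given here.

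The collection labelled female at P16 held 28 counts of Y-linked genes, a signal outside the comparisons, at 1.79 counts per 10000 against 0 to 0.0292 in the other female collections. A wrong sex label is a candidate explanation, since 5 of 5 of its cells held no Xist and a count of a Y-linked gene. A swap with a collection labelled male was ruled out by the test, as 0 of 91 such cells held Xist. Male RNA mixed into female cells was also ruled out, because 48.6 counts of Xist would be present at the level of the other female collections, where 201 of 202 cells held it, and 0 were found.

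Glial genes were higher in cholinergic and Glutamatergic than in noradrenergic cells, at a median list level of 28.9 against 5.73 counts per 10000. Of the 14 members with enough counts 100% were higher, unevenly, as in Fabp7 (6.06 against 2.18) and Mbp (0.752 against 0.674), which both glial RNA captured with the cell and transcription by these neurons could give. The chip of capture was ruled out, as the difference held in 93.3% of 15 chips with both kinds of cell (two-sided exact sign test p = 0.000977). Of these cells 5 of 20 lay at or under the upper quartile of the noradrenergic cells (17.2), and 21 of 193 noradrenergic cells lay above 28.9, so the source of the glial counts is left open. The unclassified cells, 100% of which held Th, Dbh, Slc18a2 and Slc6a2, had a median of 26.5. A high glial level was thus not particular to cholinergic and Glutamatergic cells. With the glial level as a covariate 454 genes were called in the cholinergic comparison, 409 of them also called without it, and 207 in the Glutamatergic, 191 of them also called without it, where the call of Slc17a6 was lost, a gene with 34 counts in 4 of 4 Glutamatergic cells and 0 in 193 noradrenergic cells.

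Chance as the source of the calls was tested by shuffling identities within collections, a test that identities drawn from these same transcriptomes would pass by construction. Of 31 splits, the labelled one included, 1 had as many genes called for the cholinergic comparison (highest other 26), 1 for Glutamatergic (19), and 1 each for Noradrenergic1 (16), Noradrenergic2 (11), Noradrenergic3 (28), Noradrenergic4 (18) and Noradrenergic5 (13). For Ach1 against Ach2, 2 of 31 had as many (highest other 31), so chance is not excluded for its number of calls. For sex, 7 of 21 splits of the collections had as many (highest other 19), so the number of calls is no more than chance gives.

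In 3 genes the difference between identities itself differed between the sexes in edgeR, all with the P16 collection counted as female by its label. That label is in doubt, and the fit was not repeated without this collection. For Ret it gave 1 of the 2 Ach2 libraries counted as female, each of 1 cell. Ret differed by -3.41 (SE 0.71, edgeR adjusted p = 0.0191) for Ach1 against Ach2, at 6.39 ± 6.36 (n = 3) against 5.91 ± 0.371 (n = 2) in males and 8.43 ± 5.27 (n = 4) against 2.82 ± 0.434 (n = 2) in females. Rgcc differed by 3.95 (SE 0.85, edgeR adjusted p = 0.0388) for Noradrenergic1, at 3.82 ± 2.74 (n = 3) against 0.467 ± 0.00457 (n = 2) in males and 0.576 ± 0.439 (n = 2) against 0.557 ± 0.326 (n = 7) in females. Dmkn differed by -4.01 (SE 0.80, edgeR adjusted p = 0.00642) for Noradrenergic3, at 0.129 ± 0.0509 (n = 2) against 0.648 ± 0.396 (n = 3) in males and 0.920 ± 1.04 (n = 5) against 0.813 ± 0.623 (n = 7) in females. Among the collections labelled female, Rgcc outside Noradrenergic1 was far highest in the P16 collection (1.28, a gap of 0.805 of the range). Dmkn in Noradrenergic3 was far highest in the P34 collection (2.74, 0.746).

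Single cells lay far above the others of their identity, given as level and gap over range. These were, in Ach1, Slc18a2 (7.50, 0.808) and Slc6a2 (16.9, 0.715); in Ach2, Slc18a2 (4.09, 0.561) and Slc6a2 (6.54, 0.622); and in Noradrenergic1, Slc5a7 (4.43, 0.862). Among the Glutamatergic cells they were Th (25.4, 0.948), Dbh (14.9, 0.907), Slc18a2 (10.2, 0.932) and Slc5a7 (0.546, 1).

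Single collections lay far from the others in the cholinergic comparison. On the noradrenergic side these were Vip (0.570, 0.4662) and Slc18a3 (0.0634, 0.703) in the P34 female collection, Plxnd1 in the P16 collection (0.855, 0.652) and Th in the P20 female collection (33.2, 0.523). On the cholinergic side they were Slc6a2, highest in the P31 female collection (7.17, 0.636), and Dbh, lowest in the P33 female collection (2.42, 0.574). Against Glutamatergic cells, noradrenergic Calca was highest in the P31 female (0.00908, 1) and Tac1 in the P38 male collection (0.047, 0.73). For Ach1 against Ach2 they were Crtac1 in Ach2 of the P30 female collection (0.195, 1), Kcnip4 in Ach1 of the P38 male (5.89, 0.846) and in Ach2 of the P29 male collection (0.202, 1).

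Among the noradrenergic identities, cells other than Noradrenergic1 were highest in Gabrg1 in the P33 female (0.0130, 0.76), Pde1a in the P34 female (0.0634, 0.605), Gcgr in the P20 female (0.220, 0.869), Necab1 in the P16 collection (1.71, 0.76) and Islr2 in the P11 female collection (1.07, 0.628). Dmkn outside Noradrenergic2 was highest in the P34 female collection (2.47, 0.557). 3110047P20Rik was highest in the P11 female collection both in Noradrenergic4 (1.18, 0.856) and outside it (0.0328, 0.542), Elmo1 in Noradrenergic4 of the P33 female (0.131, 1) and Chodl in Noradrenergic5 of the P29 male collection (0.154, 0.879).

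Npy lay far above the other collections in Noradrenergic4 of the P33 female (82.0, 0.777) and in Noradrenergic5 of the P34 female collection (55.8, 0.925).

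The unclassified cells, left out of every comparison, held counts of Th, Dbh, Slc18a2 and Slc6a2 in 100% of 85 cells each. Slc5a7 had a count in 10.6% (9 cells), Slc18a3 in 8.24% (7) and Chat in 4.71% (4), against 12.4%, 3.11% and 1.55% of the noradrenergic cells.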

How the results depend on the processing

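Of the alternatives described here, those with the glial covariate, without single cells and without the P16 collection for the shares were chosen after the results were seen. Over 4351 refits of named genes, 3995 kept their side of the threshold, 336 lost the call, 16 gained it and 4 reversed. Direction was compared for genes called in the main fit or in the refit, and not where both left the gene uncalled. Of 172 named calls, 110 held without each collection and 88 also in all alternatives. The reversed values were Tmem255b for Ach1 against Ach2 at 0.0212 with at least 2 cells per library (-2.92 with all), and 3 values uncalled in the main fit and called by voom. For Tmem255b the fit kept the P31 female library alone for Ach1, a collection without Ach2 cells. The voom values were Slc17a6 in Noradrenergic1 (1.78) and Noradrenergic3 (-2.09) and Chat in Noradrenergic3 (-1.56). Slc17a6 had a count in 0 and Chat in 3 of 193 noradrenergic cells, so no direction can be read for Slc17a6. The cause was not tested.

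With filterByExpr 2633 genes were tested, and calls fell to 298 cholinergic, 141 Glutamatergic, 3 for Ach1 against Ach2 and 88, 61, 56, 79 and 53 for Noradrenergic1 to Noradrenergic5. The split was 36 higher and 20 lower in Noradrenergic3 and 23 and 30 in Noradrenergic5. With at least 2 cells per library 279 cholinergic, 184 Glutamatergic and 242 Noradrenergic1 genes were called. Cells thinned to equal counts, with 22 cells fewer, gave 349 cholinergic, 133 Glutamatergic, 99 Noradrenergic1 and 52 Noradrenergic4 genes. Thinning left out 2 Glutamatergic cells, those of the P29 male collection. DESeq2 called 111, 133, 90 and 86 genes in Noradrenergic2 to Noradrenergic5. It called 186 higher and 357 lower cholinergic, 35 and 262 Glutamatergic, 1 and 18 for Ach1 against Ach2, 47 and 75 for Noradrenergic1 and 36 and 50 for Noradrenergic5; the cause was not tested. Voom called 3 for Ach1 against Ach2, 265 for Noradrenergic1, 677 for Noradrenergic3 (139 higher, 538 lower) and 75 for Noradrenergic4, with 112 higher and 149 lower for Noradrenergic2; the cause was not tested. In the simulated cholinergic data voom called 71 unchanged genes and edgeR 9. These data were drawn with dispersions that edgeR estimated, so they cannot rank the tools on the real counts. The chip as block gave 7 for Ach1 against Ach2 and 326 for Noradrenergic3. Without the block for collection 5 genes were called for Ach1 against Ach2, and this changed no other count by over 1.5 times. RLE size factors moved no split by over 10 points.

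For sex, 8 genes were called without the filter, 15 within a single chip lot (1 higher, 14 lower) and 12 over all identities, and the cause was not tested. The filter kept genes with counts in the 2 male collections alone out of the main and the single-lot fits. With an estimated correlation 8 of 39 list calls held. Held-out identities matched in 85.5% with 300 genes, 80.8% with 3000 and 83.6% with held-out chips. Shares and totals gave 0 calls in all alternatives, which for tests this small is no sign of stability. Of 64 shares of cells with a transmitter gene, 7 lay outside their interval after thinning.

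Leaving out each collection gave 348 to 567 calls for cholinergic, 91 to 360 for Glutamatergic, 5 to 17 for Ach1 against Ach2, 90 to 166, 114 to 205, 117 to 207, 87 to 152 and 56 to 174 for Noradrenergic1 to Noradrenergic5, and 2 to 6 for sex. Without the Ach1 cell richest in Npy 586 cholinergic and 17 Ach1 against Ach2 genes were called. Without the Glutamatergic cell richest in Th 379 genes were called, 180 higher and 199 lower, and with the glial covariate 207. Shuffled identities gave mostly higher calls for Noradrenergic2 to Noradrenergic5, at 93.5%, 100%, 96.8% and 93.9%, so part of the excess of increases there may come from the fit. They gave mostly lower calls in the cholinergic comparison, with 18.3% higher, and for Ach1 against Ach2, with 14% higher. Part of the excess of decreases in these comparisons may likewise come from the fit. For Glutamatergic 67.6% and for Noradrenergic1 74.8% were higher.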

Other observations

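Npy, which encodes neuropeptide Y, a vasoconstrictor peptide released with noradrenaline, had different mean levels in the noradrenergic identities. It stood at 158 ± 13.3 counts per 10000 in Noradrenergic2 (n = 7 collections) and 133 ± 14.7 in Noradrenergic3 (n = 7). It stood at 29.8 ± 23.9 in Noradrenergic1 (n = 5), 22 ± 34.3 in Noradrenergic4 (n = 5) and 11.3 ± 21.8 in Noradrenergic5 (n = 6). In edgeR it was not called, with an adjusted p of 0.0718 for Noradrenergic2 (log2 fold change 3.13) and 0.0699 for Noradrenergic3 (2.87).

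The 85 unclassified cells had a median total of 22977 counts, below that of every named identity. By the nearest profile 49 were closest to Noradrenergic3, 16 to Noradrenergic2, 10 to Noradrenergic5, 6 to Noradrenergic4, 2 to Noradrenergic1 and 2 to Ach2. Npy had a count in 85 of 85, Vip in 19, and Slc17a6 and Calca in 0 (Clopper-Pearson upper bound 4.25%). Their glial list level had a median of 26.5 counts per 10000 and their stress list level a median of 23.5.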
